A study of Mus musculus with 22 samples.

How the data were processed

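RNA levels were measured on mouse exon arrays in 22 mouse mammary cell lines, 1 array per line. Per the labels' protocols, lines were harvested while growing in culture, and total RNA was labelled with biotin by a one-cycle kit. The submitters' processing notes name GCOS, the array vendor's operating software, and the mouse genome build mm9. The background correction, the summarization of probes into transcript clusters and the normalization between arrays are not given in the sources used here. The deposited value table holds 1 value per transcript cluster and array, taken here as log2 from its range, because neither the file headers nor the labels state the scale. Values over all table entries ran from 2.74 to 13.9. Over the tested probe sets, array medians lay between 6.78 and 7.17. The SD of an array's values ranged from 1.76 in line 2855 to 2.12 in line p1522, so the arrays did not share 1 distribution.

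The table had 23332 entries. The 16755 numbered as transcript clusters in the platform annotation were tested, and the 6577 numbered otherwise were left out, apart from 1 alternative that took in every entry. Of the tested probe sets, 14996 had 1 gene symbol, 1019 had several and 740 had none, and no gene is named from a probe set with several symbols except where this is said. Gene identifiers of 14941 of the probe sets with 1 symbol were found in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. Where a gene had several probe sets, the one with the highest mean was named, which left 14860 genes. Trp53 and Krt8 were not analysed here. No column of the table belonged to a sample outside the 22.

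Lines that the labels derive from a common tumour, parent line or nodule line were averaged into 1 lineage, which gave 17 lineages. Of these, 10 came from tumours of genetically engineered mice (GEM), 5 from spontaneous tumours and 2 were immortalized lines from non-tumour mammary gland. The p-values of the group comparisons therefore measure the spread between lineages, with 1 array per line and no repeat culture of any line. Exceptions are the correlation test within and between lineages and the alternatives with each line as a replicate, which took single lines as units. The number of arrays limits the precision. The labels describe growth media for the GEM lines, and the 2 Wnt lines grew in a different medium with insulin and epidermal growth factor.

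Differences were tested with limma (lmFit and eBayes, version 3.58.1, R 4.3.3) with Benjamini-Hochberg adjustment at 0.05. GEM was set against spontaneous, and the mean of both tumour origins against immortalized, in 1 fit of all 17 lineages. The 5 GEM lineages with a Myc transgene were set against the 5 other GEM lineages in a fit of the GEM lineages alone. Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The 17 lists covered epithelial identity, luminal, basal and myoepithelial, mesenchymal, Myc targets, E2F and cell cycle, p53 targets, Wnt pathway targets, interferon response, antigen presentation, cytokines and chemokines, TGF-beta pathway, hypoxia and glycolysis, matrix proteases, and markers of immune cells, endothelium and adipocytes. Groupings, tests, lists, the rule for named genes and most alternatives were fixed before the data were examined.

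Genes were named by a fixed rule that left out predicted genes. It took the 8 largest changes past the threshold in each direction, or, where fewer passed, all that passed and up to 4 more by smallest p. It also took the 3 list members with the largest change, any list member past the threshold, and the driver genes Myc, Wnt1, Vegfa, Brca1 and Brca2. For pairs of single lines it took the 6 largest differences in each direction among probe sets whose higher value exceeded the median of its line.

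The similarity of lines was measured as Pearson correlation of gene-centred values. A one-sided permutation test with 100000 resamples compared pairs within and between lineages, and a one-sided exact permutation test compared GEM models. The epithelial minus mesenchymal score was the mean gene-centred value of the epithelial list minus that of the mesenchymal list, compared by exact two-sided permutation tests. Differences between 2 single lines had no replicate error and no test. There the median of each list was placed among 10000 random lists of the same size matched on mean level. The range holding 95% of random lists was used to describe these medians, and it was chosen after a first look at them. Random lists were drawn gene by gene, without the correlation between members of a real list. A list of correlated genes can therefore leave that range more often than a random list does. Calculations outside limma used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

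The limma step was tested on simulated data, with 200 of 16755 probe sets changed. The simulated noise was independent between probe sets and lineages, without the correlation between genes or the differing array widths of the real data. The shares below therefore do not give the error rate of the real fits. For GEM against spontaneous it recovered 78% of changes of 1 log2 unit and 98% of changes of 2 units, with 15 false calls among 191. For tumour against immortalized the shares were 53% and 95%, with 6 false calls among 154. For Myc against other GEM lineages they were 64% and 93%, with 7 false calls among 164. Alternatives covered each line as a replicate, lineage as a random block, other lineage assignments, quantile normalization, median centring, removal of the third of probe sets with the lowest mean, an intensity trend, subsets of lineages and leaving out each lineage in turn.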

Results

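The series profiled 22 mouse mammary cell lines, 12 from GEM tumours, 8 from spontaneous tumours and 2 from immortalized mammary epithelium. The GEM lines carry oncogene transgenes or deleted tumour suppressors. Lines 6DT1, cMyc and Myc83 carry Myc, MVT1 and MVT2 carry Myc with VEGF, and 2508 and 2855 carry Wnt. M6 and its lung-metastatic derivative M6C carry the SV40 T antigen, DB7 carries a mutated polyoma middle T, 780 lacks a BRCA gene that its label does not specify, and p1522 lacks p53. The spontaneous lines are 67NR, 4T07 and 4T1 from 1 tumour, D2A1 and D20R from 1 nodule line, and EMT6, F311 and TSA. EPH4 and NMUMG are the immortalized lines. Values are log2 array values, and n counts lineages unless single lines are named.

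The driver genes were read first, since they bear on the labels. Myc is the transcription factor encoded by the transgene that the labels give for 5 GEM lineages. It averaged 11.50 ± 0.40 (SD, n = 5) in those lineages and 10.61 ± 0.87 (SD, n = 5) in the other GEM lineages. The difference of 0.88 gave p = 0.0397 in an exact two-sided permutation test over 252 splits. It missed the threshold when arrays were centred on their median (exact p = 0.0556) and without any one of the ZD2508 (lines 2508 and 2855), 6DT1, cMyc, DB7, M6, MVT1 or Myc83 lineages (exact p between 0.0556 and 0.111). DB7 held the lowest Myc value, 9.16, and the difference without it was 0.52. Wnt1, a secreted ligand, read 6.04 in 2508 and 6.08 in 2855, the lines labelled with a Wnt transgene, while the spontaneous lines 4T07 and TSA read 9.21 and 8.41. Rspo2, which encodes a secreted enhancer of Wnt signalling and was picked out after its values were seen, read 8.65 in EMT6, 7.97 in D2A1 and 6.85 in D20R. Vegfa, an endothelial growth factor, read 8.90 in MVT1 and 9.30 in MVT2, within the range of the other GEM lines from 8.48 to 9.86. Brca1, a DNA repair gene, read 9.36 in the line labelled 780, the highest of the 22 lines, and Brca2 read 7.60 there, second to EPH4 at 7.62, so neither was low in the line whose label names a BRCA deletion. Where the probes lie relative to any deleted or transgenic part is not given in the sources used here, so these values do not test the labels.

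**Figure D1:**
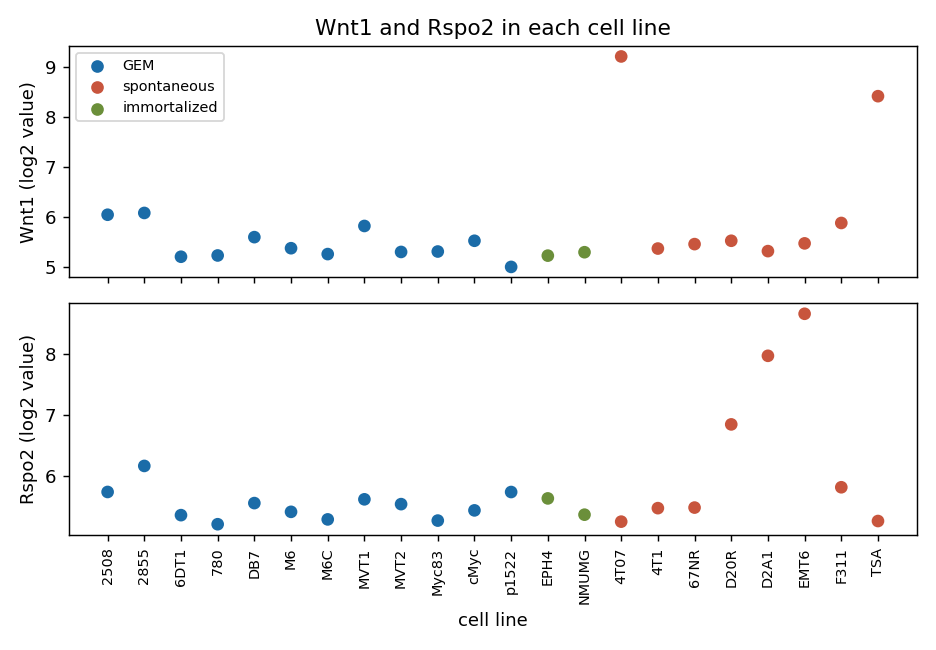
Log2 values of Wnt1 (top) and Rspo2 (bottom) in each of the 22 cell lines, 1 point per line, coloured by origin. Wnt1 reached 9.21 in 4T07 and 8.41 in TSA, and Rspo2 reached 8.65 in EMT6, 7.97 in D2A1 and 6.85 in D20R.

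The first comparison asked how lines from GEM tumours differ from lines of spontaneous tumours. Ano1, a calcium-activated chloride channel, was 3.38 log2 units higher in GEM lineages (SE 0.53), at 9.96 ± 0.87 (SD, n = 10) against 6.58 ± 1.44 (SD, n = 5). Of the spontaneous lineages, 4T read 7.83 and F311 8.43, while D2 (5.37), EMT6 (5.85) and TSA (5.44) lay below every array median, where the size of a change is uncertain near background. Slco3a1, an organic anion transporter, was 2.41 log2 units higher (SE 0.45), and Adgrl2, an adhesion receptor, 2.08 higher (SE 0.29). Serpinb8, a protease inhibitor, rose by 1.75 (SE 0.25), and Fads3, of the fatty acid desaturase family, by 1.63 (SE 0.26). The homeobox genes Hoxa6 and Hoxa5 fell by 1.48 (SE 0.28) and 1.47 (SE 0.26) in GEM relative to spontaneous lineages. Their GEM means (6.48 and 6.09) and the spontaneous mean of Serpinb8 (6.32) also lay below every array median, so these sizes are uncertain too.

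In limma, 19 probe sets of 16755 passed an adjusted p of 0.05, 9 higher and 10 lower in GEM, and 1293 had an unadjusted p under 0.05, where 838 would come by chance. Of the 19, 14 had 1 gene symbol. The other genes higher in GEM were Chmp1b, part of the membrane-scission machinery (1.19, SE 0.18), and Snap23, a membrane-fusion protein (0.74, SE 0.13). The other genes lower in GEM were Nme6 (-1.25, SE 0.18), the small GTPase Rabl2 (-1.19, SE 0.16), the mitochondrial ribosome protein Mrps26 (-0.90, SE 0.11), Gpatch4 (-0.68, SE 0.11) and the vesicle-tethering protein Trappc2l (-0.67, SE 0.13). Adjusted p among these 14 ran from 0.00194 for Mrps26 to 0.0498 for Trappc2l. Akirin2 (0.81), Rpe (0.61), Ngly1 (0.66) and Scoc (2.51) had the next smallest p among higher genes, and H4c14 (-1.14), Mrpl11 (-0.68), Ap4b1 (-0.55) and Drap1 (-0.63) among lower genes, with adjusted p from 0.0549 to 0.0737. The driver genes did not pass, at 0.43 for Myc, -0.94 for Wnt1, -0.41 for Vegfa, 0.23 for Brca1 and 0.21 for Brca2. Ano1 kept its call in 15 of 17 fits that each left out 1 lineage, while Slco3a1 kept it in 5, Hoxa6 in 5, Hoxa5 in 9 and Trappc2l in 1. The count was 10 without 4T, 9 without D2, 12 without EMT6 and 32 without 780.

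**Figure D2:**
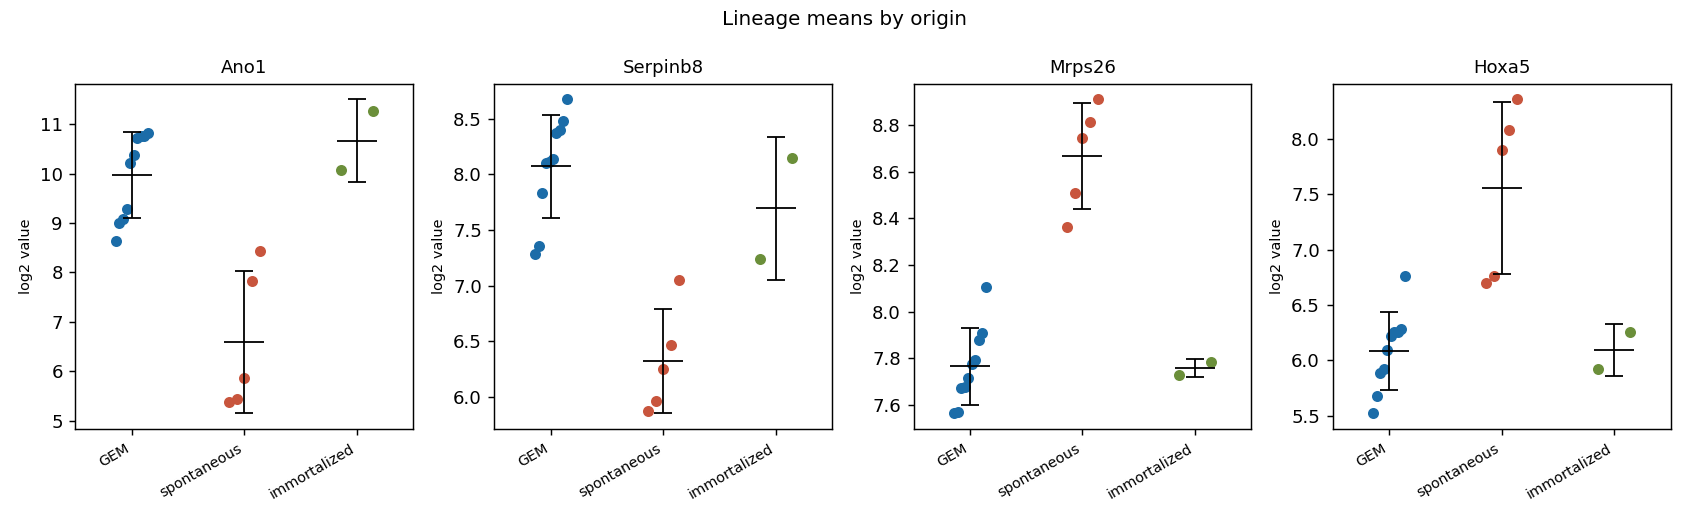
Log2 values of Ano1, Serpinb8, Mrps26 and Hoxa5, 1 point per lineage (10 GEM, 5 spontaneous, 2 immortalized), with the mean and SD of each origin as bars. Ano1 averaged 9.96 in GEM and 6.58 in spontaneous lineages, and Mrps26 averaged 7.76 and 8.67.

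Between GEM and spontaneous lineages 4 lists passed in camera with the preset correlation. With an estimated correlation no list passed: adjusted p = 0.399 for the Myc target, p53 and TGF-beta lists, and adjusted p = 0.989 for the basal list. Measured Myc targets, which serve ribosome and nucleotide synthesis, were lower in GEM at 20 of 24 genes (median -0.23, adjusted p = 3.76e-05). None of them passed over all genes, and 5 passed when adjusted over the list alone, namely Cad (-0.58, SE 0.18), Nop16 (-0.49, SE 0.15), Rrp9 (-0.41, SE 0.13), Ppan (-0.37, SE 0.09) and Nop56 (-0.32, SE 0.11). Of the p53 targets, 18 of 24 were higher in GEM (median 0.29, adjusted p = 9.32e-05), 0 over all genes and 2 adjusted over the list alone. These were Mdm2, the ubiquitin ligase that degrades p53 (1.03, SE 0.27), and Phlda3, an inhibitor of Akt (0.64, SE 0.16). The mean gene-centred value of the p53 target list was 0.26 in p1522, labelled as lacking p53. Single GEM lines ranged from -0.47 in 780 to 0.49 in 2508, so the list was not read as p53 activity. In the TGF-beta pathway, 13 of 19 genes were higher (median 0.11, adjusted p = 0.0239), 0 over all genes and 1 adjusted over the list alone, the matrix protein gene Ccn2 (1.48, SE 0.31). Basal and myoepithelial genes were higher at 13 of 16 (median 0.25, adjusted p = 0.0322), with none past the threshold over all genes or adjusted over the list alone, and the keratin gene Krt14 differed most (1.45, SE 1.02). Basal genes did not pass without ZD2508 (adjusted p = 0.456), 4T (0.0567), D2 (0.114), Myc83 (0.0704) or TSA (0.143), and TGF-beta genes not without ZD2508 (0.176), Myc83 (0.0602) or TSA (0.0692). Both lists also missed the threshold, at an adjusted p of 0.182, without 2855, F311 and 2508, the 3 arrays whose values had the smallest SD.

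The remaining lists did not pass between GEM and spontaneous lineages. Genes of epithelial identity were higher at 15 of 25 (adjusted p = 0.745), luminal genes at 10 of 16 (0.188) and mesenchymal genes at 12 of 29 (0.980). In the mesenchymal list 1 gene passed when adjusted over the list alone and 0 over all genes, the repressor of E-cadherin Zeb1 (1.41, SE 0.38). Cell cycle genes were higher at 10 of 24 (0.980), Wnt pathway targets at 8 of 14 (0.980), interferon genes at 12 of 19 (0.188) and antigen presentation genes at 7 of 11 (0.566). Cytokines and chemokines were higher at 10 of 24 (0.980), hypoxia and glycolysis genes at 11 of 16 (0.472) and matrix proteases at 10 of 18 (0.980). Markers of immune cells were higher at 3 of 13 (0.980), of endothelium at 2 of 10 (0.980) and of adipocytes at 1 of 6 (0.745). The median had the opposite sign to the test for the mesenchymal, Wnt target and immune cell lists, and the mean for the mesenchymal, Wnt target and endothelial lists.

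The second comparison set the tumour lines against the immortalized mammary lines. St6galnac4, a sialyltransferase, was 3.08 log2 units higher in tumour lines (SE 0.36), at 8.49 ± 0.58 (SD, n = 10) in GEM and 8.87 ± 0.33 (SD, n = 5) in spontaneous lineages against 5.60 ± 0.24 (SD, n = 2) in immortalized lines, a level below every array median, so the size is uncertain near background. Itgb6, the integrin subunit that activates latent TGF-beta, fell by 3.68 (SE 0.52), at 5.09 ± 0.80 in GEM and 4.91 ± 0.61 in spontaneous lineages against 8.67 ± 0.65 in immortalized lines. Tgfbr1, a TGF-beta receptor, fell by 1.49 (SE 0.28). Ereg, a ligand of the epidermal growth factor receptor, fell by 1.92 (SE 0.36), and Pfkl, a glycolytic phosphofructokinase, rose by 1.13 (SE 0.22). The Ereg means of GEM (5.95) and spontaneous lineages (5.90) lay below every array median, so its size is uncertain too.

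In all, 50 probe sets passed in limma, 19 higher and 31 lower in tumour lines, and 1993 had an unadjusted p under 0.05. Other genes that rose were H4c14, a histone H4 (1.61, SE 0.30), Mylip, a ubiquitin ligase of the LDL receptor (1.23, SE 0.22), the chromatin protein Hp1bp3 (1.10, SE 0.16), the xylosyltransferase Xxylt1 (1.03, SE 0.19), the corepressor Nab2 (0.98, SE 0.17), the helicase Fbh1 (0.90, SE 0.18) and the ribosome biogenesis gene Ppan (0.62, SE 0.13). Other genes that fell were Fgf13 (-3.41, SE 0.59), the protocadherin Pcdh7 (-3.08, SE 0.53), Sel1l3 (-2.68, SE 0.36), Tnip3, an inhibitor of NF-kappaB (-2.21, SE 0.38), the heparan sulfate enzyme Hs6st2 (-2.06, SE 0.33) and the interleukin receptor gene Il22ra1 (-2.01, SE 0.37). Among the 16 genes with the largest changes, adjusted p ran from 0.00194 for St6galnac4 to 0.0392 for Fbh1. St6galnac4, Itgb6, Sel1l3 and Hs6st2 kept their calls in 17 of 17 fits that left out 1 lineage, and Ereg did in 14, H4c14 in 13, Pfkl in 11 and Fbh1 in 7. Without EPH4 calls were lost for Fbh1 (0.45), Xxylt1 (0.70), Pfkl (0.96), Ereg (-1.61), Hp1bp3 (0.96), Nab2 (1.03), Pcdh7 (-2.96) and Tnip3 (-2.13), and without NMUMG for Il22ra1 (-0.86), Mylip (0.93), H4c14 (1.34) and Fgf13 (-2.75). The drivers did not pass, at 0.87 for Myc, 0.64 for Wnt1, 0.07 for Vegfa, -0.25 for Brca1 and -0.48 for Brca2. The Il22ra1 means of GEM (5.98) and spontaneous lineages (6.07) lay below every array median, so its size is uncertain. Of the 50 calls, 28 lay in the third of probe sets with the lowest mean, 25 of them lower in tumour lines. Itgb6, Sel1l3, Hs6st2, Fgf13, Pcdh7 and Tnip3 were among these, so the sizes of their changes are uncertain near background. There were 2 calls when that part was removed, where 22 of the 50 were still measured. The split was 59 higher and 61 lower after quantile normalization and 15 higher and 43 lower after median centring. The count was 28 without 6DT1, 32 without 4T, 32 without D2, 33 without EMT6 and 82 without TSA. Without EPH4 or without NMUMG the immortalized side was 1 array, and all 50 changes kept their sign. At 47 of the 50 both immortalized lines lay beyond every tumour lineage, so leaving 1 out could not turn the sign. The kept signs are therefore no evidence that the calls are stable.

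Between tumour and immortalized lines 4 lists passed at the preset correlation. With an estimated correlation no list passed: adjusted p = 0.797 for the Myc target, p53 and antigen presentation lists and adjusted p = 0.970 for the epithelial list. Myc targets were higher in tumour lines at 19 of 24 genes (median 0.21, adjusted p = 0.0113). Ppan passed over all genes, and 5 passed adjusted over the list alone, adding the ribosome biogenesis genes Pes1 (1.01, SE 0.21), Noc4l (0.62, SE 0.20) and Rrp9 (0.51, SE 0.18) and spermidine synthase, Srm (0.60, SE 0.21). Of the p53 targets, 17 of 24 were lower (median -0.44, adjusted p = 0.0209), of epithelial identity genes 20 of 25 (median -0.57, adjusted p = 0.0460), and antigen presentation genes were higher at 10 of 11 (median 0.38, adjusted p = 0.0467). In these 3 lists 0 genes passed over all genes and 0 adjusted over the list alone. Cdh1, the epithelial cadherin, differed by -2.90 (SE 1.38), the p53 target Trp53inp1 by -1.77 (SE 0.60; 7.32 in EPH4, 9.53 in NMUMG) and the proteasome subunit gene Psmb9 by 0.94 (SE 0.39). The Myc target and p53 calls were lost without NMUMG (adjusted p = 0.117 and 0.717), while the epithelial call was kept in 7 and the antigen presentation call in 9 of 17 fits that left out 1 lineage. Without EPH4 the epithelial list had an adjusted p of 0.924.

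Of the lists that did not pass between tumour and immortalized lines, the TGF-beta pathway was lower at 11 of 19 genes (adjusted p = 0.110). It held Itgb6 and Tgfbr1, which passed over all genes, and 4 genes passed adjusted over the list alone, adding the ligand Tgfb3 (1.02, SE 0.35) and the pseudoreceptor Bambi (0.63, SE 0.21). Hypoxia and glycolysis genes were higher at 13 of 16 (0.0862), with Pfkl past both adjustments. In 5 further lists 1 gene each passed adjusted over the list alone and 0 over all genes, and the lists themselves did not pass. These were Vim, an intermediate filament of mesenchymal cells, at 2.30 (SE 0.61) among mesenchymal genes (17 of 29 higher, 0.0998) and the mucin Muc1 at -1.51 (SE 0.44) among luminal genes (10 of 16 higher, 0.907). Each rests on 1 immortalized line, Vim on EPH4 (8.37, against 12.89 in NMUMG) and Muc1 on NMUMG (9.22, against 6.10 in EPH4), while the other line lay at the tumour mean (12.94 and 6.12 in GEM). The others were the proliferation marker Mki67 at -1.14 (SE 0.31) among cell cycle genes (16 of 24 higher, 0.791), the stem cell marker Lgr5 at -0.73 (SE 0.16) among Wnt targets (10 of 14 higher, 0.799) and the chemokine Cx3cl1 at 1.76 (SE 0.48) among cytokines and chemokines (14 of 24 higher, 0.791). The Lgr5 means of GEM (5.17), spontaneous (5.23) and immortalized lineages (5.93) all lay below every array median, so its size is uncertain near background. Basal genes were higher at 9 of 16 (0.791), interferon genes at 17 of 19 (0.0862), matrix proteases at 10 of 18 (0.907) and markers of immune cells at 7 of 13 (0.915), endothelium at 8 of 10 (0.788) and adipocytes at 2 of 6 (0.907). The median and the test had opposite signs for the luminal, basal, cytokine, matrix protease, immune cell and adipocyte lists.

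The third comparison set GEM lineages with a Myc transgene against those with other drivers. Has2, which makes hyaluronan for the extracellular matrix, fell by 3.57 log2 units in Myc lineages (SE 0.24), at 5.93 ± 0.26 (SD, n = 5) against 9.50 ± 0.53 (SD, n = 5), and the size is uncertain because the Myc lineage mean lies below every array median. Fst, the secreted activin-binding protein follistatin, was 4.20-fold lower, at 7.53 ± 0.25 against 9.60 ± 0.18. The activin subunit gene Inhba differed by -2.49 (SE 0.61) and Timp3, an inhibitor of matrix proteases, by -4.01 (SE 0.65), and neither passed over all genes. The Myc lineage mean of Timp3 (6.26) also lay below every array median, so its size is uncertain.

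Has2 and Fst, both lower, were the 2 calls in limma (adjusted p = 0.000184 for each), and 906 probe sets had an unadjusted p under 0.05. The next genes by p did not pass. Those were Spg20 (0.83), Serpinb9c (0.87), Bmp7 (1.98) and Hacd4 (1.74) among higher genes and Gsta4 (-3.07), Hey1 (-1.92), Timp3 and Rgs16 (-1.24) among lower genes, with adjusted p from 0.0636 to 0.383. The other drivers differed by -0.01 for Wnt1, -0.27 for Vegfa, -0.42 for Brca1 and -0.53 for Brca2, and Myc had an adjusted p of 0.900 in limma. Has2 and Fst kept their calls in 10 of 10 fits that left out 1 lineage, and the count was 15 without p1522. Neither passed when all lineages shared 1 fit of 4 groups (adjusted p = 0.0546 for Has2 and 0.166 for Fst), which called 0 probe sets, with 924 at an unadjusted p under 0.05.

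**Figure D3:**
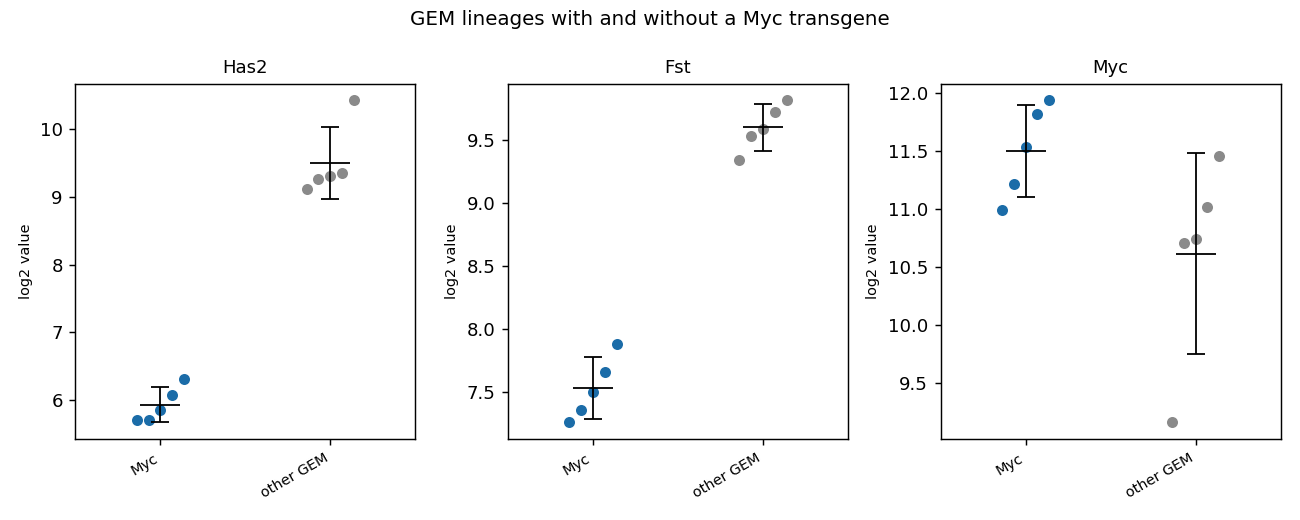
Log2 values of Has2, Fst and Myc in the 5 GEM lineages with a Myc transgene and the 5 with other drivers, 1 point per lineage, with the mean and SD of each group as bars. Has2 averaged 5.93 against 9.50, Fst 7.53 against 9.60 and Myc 11.50 against 10.61.

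Between Myc and other GEM lineages 6 lists passed at the preset correlation, the interferon, cytokine, antigen presentation, epithelial and TGF-beta lists lower and the hypoxia list higher in Myc lineages. With an estimated correlation no list passed: adjusted p = 0.0609 for cytokines and chemokines, adjusted p = 0.798 for epithelial identity and adjusted p = 0.280 for the other 4. Interferon response genes were lower at 19 of 19 (median -0.93, adjusted p = 1.44e-13), including the antiviral genes Ifit1 (-2.69, SE 0.94) and Oasl2 (-1.80, SE 0.69). The mean gene-centred value of the interferon list was 2.12 in 780, 1.31 in p1522 and 0.82 in DB7, against -0.65 in M6, -0.46 in M6C, -0.40 in 2508 and -0.08 in 2855, and Myc lineages ran from -0.59 in cMyc to 0.03 in 6DT1. Cytokines and chemokines were lower at 20 of 24 (median -0.49, adjusted p = 1.76e-08) and antigen presentation genes at 7 of 11 (median -0.35, adjusted p = 0.00149), led by the immunoproteasome gene Psmb8 (-1.65, SE 0.54). Epithelial identity genes were lower at 23 of 25 (median -0.54, adjusted p = 1.83e-04), with Epcam at -1.59 (SE 1.49), and TGF-beta pathway genes at 13 of 19 (median -0.30, adjusted p = 0.00449). Hypoxia and glycolysis genes were higher at 13 of 16 (median 0.28, adjusted p = 0.00286), among them the glucose transporter Slc2a1 (1.16, SE 0.37). No gene of these 6 lists passed over all genes. Adjusted over the list alone, the chemokines Cxcl5 (-2.96, SE 0.70) and Cxcl16 (-2.11, SE 0.51) and the TGF-beta list's Inhba passed, and 0 genes of the other 4 lists did. The Myc lineage means of Cxcl5 (5.67), Cxcl16 (6.47), Ifit1 (5.78), Oasl2 (6.66) and Psmb8 (6.04) lay below every array median. The sizes of these changes are therefore uncertain near background. The epithelial call was lost without M6 (adjusted p = 0.222) and the TGF-beta call without ZD2508 (adjusted p = 0.140).

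Myc targets themselves were higher at 14 of 24 genes in Myc lineages (median 0.05, adjusted p = 0.821), with 0 genes past either adjustment. The luminal list was higher at 8 of 16 genes (0.782) and held Gata3, a luminal transcription factor, at 1.27 (SE 0.27). The matrix protease list was higher at 8 of 18 (0.461) and held Timp3 and the plasminogen activator Plat at 1.10 (SE 0.29). Gata3, Timp3 and Plat passed adjusted over the list alone and not over all genes. Basal genes were higher at 6 of 16 (0.821), mesenchymal genes at 12 of 29 (0.241), cell cycle genes at 10 of 24 (0.388), p53 targets at 12 of 24 (0.913) and Wnt pathway targets at 7 of 14 (0.782). Markers of immune cells were higher at 11 of 13 (0.268), of endothelium at 9 of 10 (0.268) and of adipocytes at 6 of 6 (0.206). The median had the opposite sign to the test for the Wnt target list, and the mean for the luminal list.

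The balance of epithelial and mesenchymal genes differed widely between lines. M6 and M6C scored highest, at 2.52 and 2.42, followed by 4T1 at 1.74, EPH4 at 1.72 and F311 at 1.55. The lowest scores were those of 67NR at -1.49, p1522 at -1.45 and 780 at -1.40. Cdh1 read 11.8 in M6 and 6.64 in 67NR, and Vim read 8.37 in EPH4 against 12.3 in M6C, the next lowest line. GEM lineages averaged -0.09 ± 1.27 (SD, n = 10) and spontaneous lineages -0.16 ± 1.17 (SD, n = 5), a difference of 0.07 (exact two-sided permutation p = 0.923, 3003 splits). Myc lineages averaged -0.27 ± 0.70 (SD, n = 5) and other GEM lineages 0.10 ± 1.74 (SD, n = 5), a difference of -0.37 (exact two-sided permutation p = 0.722, 252 splits). Both differences were smaller than the spread between lineages. The sign of the first turned without DB7 (-0.09), M6 (-0.23), Myc83 (-0.04), D2 (-0.16), EMT6 (-0.07) or TSA (-0.16), and that of the second without M6 (0.25).

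**Figure D4:**
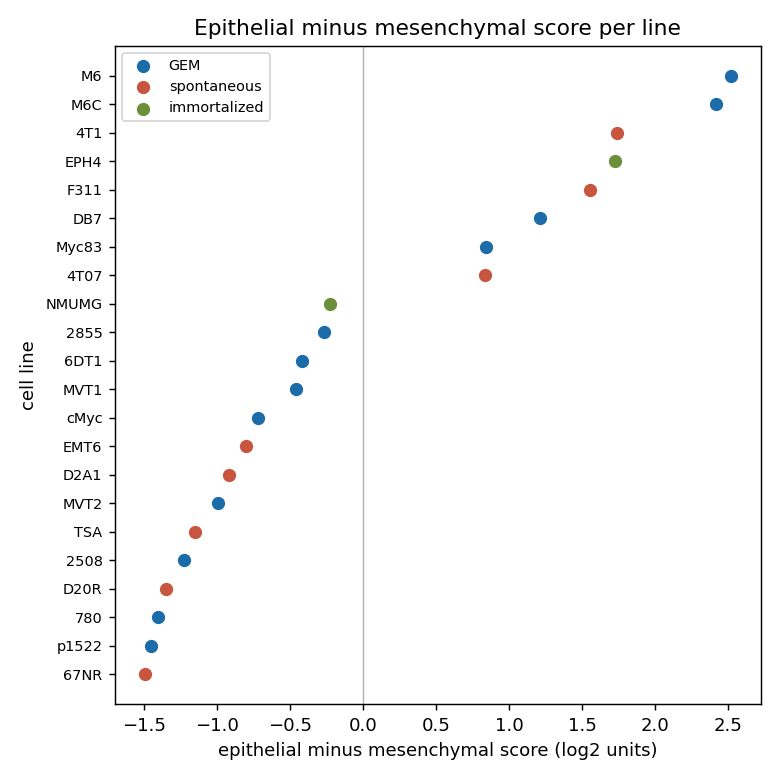
Epithelial minus mesenchymal score (log2 units) of each of the 22 lines, sorted, 1 point per line, coloured by origin. Lines of each tumour origin lie at both ends, from 2.52 in M6 to -1.49 in 67NR.

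Lines of 1 lineage were on average more alike than lines of different lineages, though not in every pair. The gene-centred correlation averaged 0.321 ± 0.329 (SD, 6 pairs) within lineages and -0.056 ± 0.178 (SD, 225 pairs) between lineages, a difference of 0.376 (one-sided permutation p = 0.00054). M6 and M6C correlated at 0.739, 2508 and 2855 at 0.514 and 4T1 and 4T07 at 0.448, while 67NR correlated with 4T07 at 0.041 and with 4T1 at -0.164. The nearest line was of the same lineage for 8 of 9 lines, the exception being 67NR, whose nearest line was EMT6 at 0.133. Between GEM models, 6DT1 and MVT1 correlated at 0.660. Lineages of 1 model averaged 0.107 ± 0.331 (SD, 4 pairs) and of different models -0.041 ± 0.249 (SD, 41 pairs), a difference of 0.148 that did not pass (one-sided exact permutation p = 0.125, 2520 assignments). Myc alone and Myc with VEGF counted as different models here. Pairs that share a Myc transgene, such as 6DT1 with MVT1 or with MVT2 (0.505), thus fell among the different models. The test does not ask whether a shared Myc transgene makes lineages alike.

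The lines of the 4T lineage differ, per their labels, in spread from the mammary gland, with 67NR described as staying in place, 4T07 as reaching the lung without growing there, and 4T1 as metastatic. Each is 1 array, so differences are given without a test. Epithelial genes read higher in both 4T1 and 4T07 than in 67NR. The median of the epithelial list was 2.07 higher in 4T1 (25 of 25 genes) and 1.17 higher in 4T07 (19 of 25), each above all 10000 random lists. The largest differences between 4T1 and 67NR were Perp, a desmosomal p53 target (6.14), the serine protease Tmprss11e (5.85), the collagen-binding integrin Itga2 (5.59), the cytokine Il1a (5.54), Mal2 (5.43) and Pcgf6 (5.21). In the other direction stood the progenitor surface protein Cd34 (-6.16), podoplanin, Pdpn (-5.81), epoxide hydrolase Ephx1 (-5.63), N-cadherin, Cdh2 (-5.21), Aldh1l2 (-5.07) and Mxra8 (-5.04). In 4T07 relative to 67NR, the cytokine Tslp (6.10), Perp (5.54), keratin gene Krt18 (5.16), Pcgf6 (5.09), Amigo2 (5.06) and Tmem47 (4.81) read higher. Cd34 (-6.30), Pdpn (-6.18), Ephx1 (-5.45), Cdh2 (-5.35), Epb41l3 (-5.05) and Stbd1 (-4.95) read lower there. In both pairs the lower reading of each named gene lay below every array median, so sizes and order are uncertain near background. The exceptions were Pdpn in 4T1 (6.84) and Amigo2 in 67NR (6.85). Mesenchymal and p53 target lists lay below the range of 95% of random lists in both lines, with medians of -0.36 and -0.66 in 4T1 and -0.43 and -0.62 in 4T07. TGF-beta (0.58), cytokine (0.32) and interferon (0.12) genes lay above it in 4T1, and cell cycle genes (-0.29) below it in 4T07.

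Between 4T1 and 4T07, inflammatory and epithelial genes read higher in 4T1. Il1a differed by 5.77, the actin-bundling protein Lcp1 by 5.57, Mal2 by 4.51, Tmprss11e by 4.15, the growth factor Bmp7 by 4.08 and the epithelial GTPase Rab25 by 3.98. Tmem47 (-4.88), the urea transporter Slc14a1 (-4.74), the retinol transporter Stra6 (-4.31), Efemp1 (-4.08), Prr11 (-4.00) and the adhesion molecule Cadm1 (-3.90) read lower in 4T1. Except for Tmprss11e in 4T07 (6.94) and Stra6 in 4T1 (6.82), the lower reading of each lay below every array median. Those sizes are uncertain near background. Medians above the range of 95% of random lists were those of cytokines and chemokines (0.74), epithelial identity (0.59), the TGF-beta pathway (0.38), antigen presentation (0.24), interferon response (0.23) and Myc targets (0.13). Those below it were hypoxia and glycolysis (-0.28) and matrix proteases (-0.18). Of 17 lists, 8 lay outside that range in this pair, 6 between 4T1 and 67NR and 4 between 4T07 and 67NR. Because random lists lack the correlation within real lists, no error rate can be given for these counts. After quantile normalization the counts were 8, 7 and 6, with Myc targets added between 4T1 and 67NR, and interferon and TGF-beta genes between 4T07 and 67NR. Genes more than 2 log2 units apart numbered 45 higher and 52 lower in 4T1 than in 4T07, against 289 higher and 198 lower in 4T1 than in 67NR, and 214 higher and 135 lower in 4T07 than in 67NR.

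M6C, from a lung metastasis of M6, differed from it by more than 2 log2 units at 14 genes higher and 1 lower. The largest were the neuronal tubulin-binding gene Stmn2 (5.35), metallothionein Mt2 (5.09), the matrix proteoglycan Vcan (3.85), Trim29 (3.53), Vsnl1 (2.67) and the tight junction gene Cldn1 (2.56). On the lower side were Pip5k1b (-2.33), connexin Gjc1 (-1.92), the epithelial transcription factor Ehf (-1.87), the lymphatic growth factor Vegfc (-1.80), Taar7b (-1.79) and Ptprn (-1.73). Except for Cldn1 in M6 (7.11) and Taar7b in M6C (8.74), the lower reading of each gene lay below every array median. Those sizes are uncertain near background. Matrix proteases lay above the range of 95% of random lists (median 0.22), and Myc targets (-0.16), cytokines and chemokines (-0.28) and mesenchymal genes (-0.19) lay below it, as they did after quantile normalization. Interferon genes (0.08) lay above the range and moved inside it after quantile normalization, while epithelial genes moved below it. D2A1 and D20R, whose label describes tests of metastatic ability without naming a result, differed by more than 2 units at 56 genes higher and 91 lower in D2A1. Akr1c18 (4.71), the guidance ligand Slit2 (3.56), Cpne8 (3.41), Plscr2 (3.15), Pcbd1 (3.03) and the coagulation inhibitor Tfpi (2.91) read higher in D2A1. The amino acid transporter Slc38a1 (-5.37), Creb3l1 (-4.93), Prss23 (-4.90), AU018091 (-4.85), Mbnl3 (-4.80) and the matrix protein tenascin, Tnc (-4.79) read lower. In this pair too the lower readings lay below every array median, except for Plscr2 (7.14) and Pcbd1 (7.65) in D20R. Interferon genes lay above the range of 95% of random lists in D2A1 (median 0.43), and TGF-beta (-0.35), epithelial (-0.35) and mesenchymal (-0.31) genes lay below it. Matrix proteases (-0.26) lay below the range and moved inside it after quantile normalization, while hypoxia and glycolysis genes moved above it. Over the 5 pairs of lines, 41 of 85 list medians moved by more than the SD of random lists after that normalization, and 0 of those outside the range turned sign.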

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

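The tests with array SD as a covariate and the reading of the probe set shared by H2-T10 and H2-T22 were chosen only after the data were seen. Of 106 groups of lineages tested for a value far from the rest, 7 stood out, where 5.3 would by chance. Fgf13 read 8.30 in M6, against 5.68 in the next GEM lineage. Hs6st2 read 5.71 and Pcdh7 read 7.35 in ZD2508, each the highest of the GEM lineages. Myc read 9.16 and Trappc2l read 8.42 in DB7, each the lowest of the GEM lineages. Hey1, a Notch target, read 9.92 in D2, and Snap23 read 10.8 in TSA, each the highest of the spontaneous lineages.

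For the genes called between GEM and spontaneous lineages, 100 splits of the 15 tumour lineages were drawn, the real one included. Of these, 2 called as many as the real 19, a share under a 5% bound set beforehand. That share takes lineages as interchangeable, so it does not exclude chance. The 1 other split called 1933, with ZD2508, 4T, EMT6, F311 and MVT1 against the rest. That split points to a structure of the samples that goes at least in part with array width, as the mean array SD was 1.93 in those 5 lineages and 2.04 in the rest, and with the SD as a covariate it called 0 (954 at an unadjusted p under 0.05) and the 1933 changes shrank to a median ratio of 0.461. Array width was argued against as the whole cause of the real 19, because all 19 calls held with the SD of each array as a covariate, which moved the changes by a median ratio of 1.01. Genetic background cannot be told apart from origin, since the labels give BALB/c or a foster-nursed BALB/c strain for 4T, EMT6, F311 and TSA: EPH4, a BALB/c line not from a tumour, lay nearer the spontaneous mean at 15.8% of the calls, under a bound set beforehand to exclude that cause, but NMUMG gave the same 3 of 19 and the bound rested on 1 line, and the bound was set aside after this value was seen. The probe set shared by H2-T10 and H2-T22, major histocompatibility genes that differ between strains, read 3.17 in EPH4, 3.79 to 5.98 in spontaneous, 8.40 in NMUMG and 8.22 to 10.9 in GEM lineages, so strain may account for that call, and tumour origin stays open for the others.

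The genes called between Myc and other GEM lineages were weighed next. Of 100 drawn splits of the 10 GEM lineages, the real one included, 3 called as many as the real 2. That share lay under a 5% bound set beforehand. It takes lineages as interchangeable, which their correlations go against, so chance is not excluded. Of the other splits, 1 called 326. That split set 6DT1, cMyc, MVT1, MVT2 and p1522 against the rest and points to a structure of the samples, as 6DT1 correlated with the other 4 at 0.399 to 0.660 and with Myc83 at -0.192, while low epithelial minus mesenchymal scores (-1.45 to -0.42) were shared by 780 and 2508 on the other side. The medium of the Wnt lines was not a requirement for the calls, as 3 probe sets, both Has2 and Fst among them, were called without those lines. Driver identity stays among the open explanations.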

How the results depend on the processing

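The array SD covariate, the fits without 2855, F311 and 2508, the fits with every table entry and the leave-outs of gene lists, scores and driver Myc were chosen only after the data were seen. No paired analysis was possible because the labels give no replicate numbers shared between groups. For GEM against spontaneous, the 19 calls became 91 with each line as a replicate and 42 with the SD covariate, each including all 19. With lineage as a random block there were 12 calls, and only 8 of the 19 were among them. The count was 9 to 32 when 1 lineage was left out. For tumour against immortalized, the 50 calls became 103 with each line as a replicate, 120 after quantile normalization, 2 without the third of probe sets with the lowest mean, 473 with the SD covariate (306 higher, 167 lower) and 412 with every table entry (79 higher, 333 lower), and 28 to 413 when 1 lineage was left out. For Myc against other GEM, the 2 calls became 4 with each line as a replicate and 0 with all lineages in 1 fit, and 2 to 15 when 1 lineage was left out. With an estimated correlation 0 lists passed, and with fry for a common direction 0, in each comparison. The mixed form of fry, which asks for changes in either direction, passed for Myc targets in GEM against spontaneous (adjusted p = 0.00759). In tumour against immortalized that form passed for Myc targets (adjusted p = 0.00106) and the TGF-beta pathway (adjusted p = 1.77e-06). With camera at the preset correlation, 4 lists passed in GEM against spontaneous, 2 without the 3 narrowest arrays and 2 to 6 when 1 lineage was left out (2 without ZD2508, Myc83 or TSA). In tumour against immortalized it was 4, and 1 to 7 when 1 was left out (1 without NMUMG, 7 without M6, 2 without ZD2508, 6DT1, 780, EMT6, MVT1 or p1522), and in Myc against other GEM 6, and 6 to 9. The Myc driver difference was 0.90 with an exact p of 0.0556 after median centring, and 0.52 to 1.09 when 1 lineage was left out. The epithelial minus mesenchymal difference ran from -0.23 to 0.51 for GEM against spontaneous and from -0.73 to 0.25 for Myc against other GEM when 1 lineage was left out. It turned sign without DB7 (-0.09), M6 (-0.23), Myc83 (-0.04), D2 (-0.16), EMT6 (-0.07) or TSA (-0.16) in the first, and without M6 (0.25) in the second. Apart from the low preset correlation of the lists, the cause of these changes was not tested. It is known only that fewer probe sets were tested without the dimmest ones and fewer lineages in the leave-outs. Of 190 alternative values of main results, 135 kept their direction and side of the threshold or stayed within 1.5 times the count. Of 995 for single genes and lists, 799 did so, 155 no longer passed and 41 moved. Those 41 were all among the 85 list medians of pairs of single lines, after quantile normalization. Of the medians outside the range of random lists used above, 0 turned sign. Some medians inside that range did turn, such as that of interferon genes in 4T07 relative to 67NR, from -0.08 to 0.13. The named genes past the threshold kept their sign. Of the 50 tumour against immortalized calls, 28 were among the dimmest probe sets, where signal over background limits them.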

Other observations

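The tests on Wnt1 and Rspo2 below were chosen only after their values had been seen, and the choice of genes in the next paragraph was made in the same way. The epithelial cadherin gene Cdh1 fell into 2 clusters of lines, from 10.5 to 11.8 in 10 lines and from 6.28 to 7.30 in the other 12. Zeb1, a repressor of Cdh1, did not follow it in every line. It read 8.06 in 2855, 8.25 in Myc83 and 7.46 in DB7, where Cdh1 was high, and 5.95 in TSA and 6.42 in EMT6, where Cdh1 was low. F311, which its label calls sarcomatoid, read 10.5 for Cdh1. The basal keratin gene Krt5 read 12.2 in 2508 and 6.54 in 2855, lines whose labels name the same tumour.

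Wnt1 at 9.21 in 4T07 and 8.41 in TSA, and Rspo2 in EMT6 and the D2 lines, were the third pattern weighed. Mixing of 4T07 and TSA cells was argued against, since the 54.5% of 4T07 cells that would give TSA its Wnt1 level would need a Cdh1 level 10.1 there, and TSA read 6.45, a gap of -3.69. A candidate explanation is activation by integrated mouse mammary tumour virus, for which Wnt1 and Rspo2 are known target genes: spontaneous lines held more high values in the 14 measured genes of a list of 16 such genes than 99.99% of random lists, but without Wnt1 and Rspo2, a check added once that value was seen, the share was 95.34% by lines and 89.74% by lineages, so the test cannot decide. Whether the Wnt pathway was active in 4T07 also cannot be told apart, as its targets lay at percentile 64.0 of random lists against the mean of 4T1 and 67NR, with Axin2 at 0.84 and Lef1 at -0.25. No virus sequence was analysed here.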
